A study of Arabidopsis thaliana with 21 samples.

How the data were processed

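Roots of Arabidopsis thaliana accession Col-0 were profiled on 21 Affymetrix ATH1 arrays, a single-colour platform that reports a signal for each probe set, hybridised with biotin-labelled material made from total RNA. The deposited values were signal intensities on a linear scale, made by the authors with the MAS5 algorithm, per the labels. The version of MAS5 and its settings are not given in the sources used here. In every deposited column the mean after removal of the lowest and highest 2% of values was 100 to within 0.01, so each array had been scaled by the authors to a common mean, and that scaling was kept. Detection calls and scanner files were not used here. Each column held 1 array, and no replicates had been pooled.

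The arrays carried 22810 probe sets, of which 64 were Affymetrix control probe sets and were left out of the tests. Of the other probe sets, 13513 had 1 gene in the platform annotation used here, 503 had several and 8730 had none. Names were taken only from that annotation and from a table of locus tags and symbols. A gene was named only from a probe set with 1 gene. Unnamed probe sets were tested and counted but are not discussed singly.

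A probe set was tested when its signal exceeded its array's 40th percentile on at least 3 of the 21 arrays, which left 15284 probe sets, 8331 of them with 1 gene. Signals were taken to log2 with no pseudocount. A model with a mean for each of the 7 groups was fitted to all 21 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend, 14 residual degrees of freedom). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each of 8 comparisons, and adjusted p < 0.05 was the threshold. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Levels are mean signals ± SD over arrays of a group, and a value after ± for a log2 difference is the standard error of the fit.

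The comparisons, the model, the filter, 24 gene lists with 535 members and the rule for naming genes were chosen before the data were examined. Named genes were the 8 largest fitted rises and 8 largest fitted falls of each comparison among probe sets that passed, whose arrays did not overlap between the groups compared and whose brighter group exceeded the 40th percentile on all its arrays. For the difference between the sucrose effects, where overlap has no meaning, neither of these last criteria was applied, so dim genes could be named. In addition, up to 3 members with the smallest adjusted p were named from each list that passed its test. The text gives only some of these genes and does not follow their rank. Which of them it gives was not set by a rule. With 3 arrays against 3, chance alone separates 10% of unchanged genes completely. Where all arrays of a group, also of 1 group of a combined side, lay below their 40th percentile, the fold was computed with each dim array set at the higher of that percentile and its own value, and is given as at least N-fold. No fold is given where all arrays of both groups lay below it.

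Lists were tested with camera in limma, with a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. A list needed at least 3 tested members with a named probe set. The 10 lists that had them covered photosynthesis and shoot tissue, sugar starvation, starch and sucrose metabolism, iron deficiency, cell cycle, root hair, glucosinolate synthesis, hypoxia, heat shock and auxin response. Most of their members had no named probe set. In the order given, 9 of 47, 4 of 25, 5 of 29, 4 of 25 and 3 of 34 members had one. For the later lists it was 5 of 29, 4 of 34, 5 of 19, 5 of 17 and 8 of 18. Counts of genes in a list are over tested members, not over the whole list. Plastid-encoded probe sets (66) and mitochondrion-encoded probe sets (16) were tested in the same way as a pair of their own. The annotation gave no locus tag for mitochondrial genes, and probe sets with a lower-case symbol and no locus tag were taken as mitochondrion-encoded. Single members of the lists on flavonoids, sulfur deficiency, the Casparian strip, xylem, defence, dehydration, the evening clock, senescence and cytokinin are reported as genes. The lists on nitrogen, phosphate starvation, suberin, aquaporins and the morning clock had no tested member with a named probe set and gave no result.

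Alternatives changed 1 choice at a time. They were quantile normalization, centring each array on its median, no filter, a filter at the 60th percentile, a pseudocount of 6.99 (the median over arrays of the 20th percentile), eBayes without the intensity trend, only the arrays of the groups compared, the replicate letter as a block, an estimated correlation for lists, and leaving out each array in turn. Added after the data were seen were either soil group alone against GM and a test of 20 families of genes that share the letters of their symbol, also run under both other scalings. Splits of the arrays into other groups of the same sizes were refitted, all 10 for 3 against 3 arrays, all 100 pairs of such splits for the difference of sucrose effects, all 84 for 3 against 6, and 100 drawn with a fixed seed for soil against GM, the real split included.

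The pipeline was tested on simulated data with normal noise of each probe set's own mean and residual SD, 15284 probe sets and 50 changed ones for each true fold. At a true fold of 2, the share recovered with the right sign ran from 90% to 98% over the comparisons, except for the difference of sucrose effects, where it was 72%. At a true fold of 1.5 it ran from 64% to 88%, and was 36% for that difference. False calls made up between 1.60% and 7.07% of all calls. The simulated noise was independent between probe sets, and 200 of them were changed, far fewer than passed in the real comparisons. These shares therefore need not hold for the real data. The number of arrays limits the precision of every value.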

Results

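Transcript levels were measured in roots of Arabidopsis thaliana Col-0 on 21 ATH1 arrays in 7 groups of 3. Groups ATGE_3 and ATGE_9 grew on soil in continuous light at 23 °C and 65% relative humidity, which is not given for the other groups, and the labels of ATGE_3 state that soil came with the sampled tissue. Groups ATGE_94 and ATGE_98 grew in continuous light at 20 °C on 0.5x GM, a nutrient medium for plates, and groups ATGE_95 and ATGE_99 on the same medium with 5% sucrose listed. The labels do not say how much sucrose GM itself held. Group ATGE_93 grew in long days at 22 °C on 1x MS, another plate medium, with 1% sucrose. The labels liken most plants of ATGE_94 and ATGE_95 to 7-day-old plants of a reference set, and ATGE_9, ATGE_98 and ATGE_99 are known as later harvests of the developmental series. Median signals ran from 38.7 to 45.2 over the arrays, and the 40th percentiles, below which a signal was treated as dim, from 22.9 to 28.0. Across probe sets, which are not independent replicates, arrays of a group correlated with r between 0.977 and 0.987. The first principal component held 56.4% of the variance and set the soil arrays apart from the plate arrays, and the next held 14.6%. The 3'/5' signal ratio of the GAPDH control, a measure of RNA integrity, ran from 0.977 ± 0.0209 in ATGE_93 to 1.38 ± 0.0626 in ATGE_3 (SD, n = 3). That of actin was 2.38 ± 0.104 in ATGE_3, 1.76 ± 0.140 in ATGE_9, 1.38 ± 0.0923 in ATGE_93, 1.85 ± 0.426 in ATGE_94, 2.81 ± 0.783 in ATGE_95, 2.07 ± 0.185 in ATGE_98 and 1.58 ± 0.106 in ATGE_99. No label says that replicates were separate cultures, so each p-value measures the spread between these samples.

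The earlier plate sets asked what 5% sucrose changed in the root, ATGE_95 against ATGE_94. MCCA (AT1G03090) and IVD (AT3G45300), both of leucine breakdown, were lower with sucrose. MCCA, a subunit of methylcrotonyl-CoA carboxylase, fell from a signal of 447 ± 34.4 to 133 ± 7.07 (3.35-fold, SD, n = 3). IVD, isovaleryl-CoA dehydrogenase, fell from 409 ± 31.1 to 141 ± 7.52 (2.90-fold). The peroxidase gene AT1G34510 rose 8.20-fold, from 31.9 ± 7.07 to 258 ± 24.5, its relative AT3G49960 5.25-fold, from 99.1 ± 7.17 to 520.1 ± 38.8. EXPA18 (AT1G62980), an expansin of root hairs, rose 3.01-fold, from 158 ± 6.16 to 476 ± 26.46. BCAT4 (AT3G19710), which starts the chain elongation of methionine for glucosinolates, rose 2.93-fold, from 137 ± 9.18 to 399.5 ± 5.67.

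Among the other large changes in this comparison, OCT1 (AT1G73220), a carnitine transporter, lay at 40.4 ± 5.97 with sucrose against a dim 2.03 ± 0.454, at least 1.67-fold higher. XTH26 (AT4G28850), a xyloglucan-modifying enzyme, was at least 3.53-fold higher at 86.2 ± 22.1, and AT5G20790 at least 5.15-fold higher at 124 ± 10.01. MGL (AT1G64660), methionine gamma-lyase, fell 4.43-fold, from 273 ± 5.06 to 61.6 ± 3.43, and GAT1_2.1 (AT1G15040), an amidotransferase-like protein, 4.57-fold, from 733 ± 41.9 to 161 ± 24.2. AT1G19530 fell 8.47-fold, from 180.1 ± 16.4 to 22.1 ± 8.06, AT1G73120 6.02-fold, and AT5G56100 5.52-fold. BHLH101 (AT5G04150), a transcription factor of iron deficiency, was at least 1.78-fold lower than its 41.8 ± 2.01 on GM alone.

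Of the lists, sugar starvation fell in 4 of 4 measured genes, and in 4 when adjusted over the list alone (median log2 −1.25, camera adjusted p = 3.2e-08, adjusted p = 0.0032 with an estimated correlation). Besides MCCA and IVD they were AKINBETA1 (AT5G21170), a subunit of the SnRK1 kinase complex, at −0.93 ± 0.08, and AT3G15450 at −0.96 ± 0.06. Root hair genes rose in 4 of 5, or 5 when adjusted over the list alone (median 1.23, adjusted p = 5.7e-06, adjusted p = 0.0032 with an estimated correlation). These were XTH26, EXPA18, EXPA7 (AT1G12560) and the peroxidase gene AT1G30870, and SCN1 (AT3G07880) gave 0.14 ± 0.06. Glucosinolate synthesis rose in 4 of 4, and in 4 adjusted over the list alone (median 1.45, adjusted p = 8.5e-07, adjusted p = 0.0050 with an estimated correlation). Examples were GSTU20 (AT1G78370), a glutathione transferase, at 1.60 ± 0.13, AT2G31790, a glucosyltransferase gene, at 1.36 ± 0.09 and UGT74B1 (AT1G24100) at 0.35 ± 0.07. Photosynthesis genes fell in 6 of 9, or 7 adjusted over the list alone. LHCB4.1 (AT5G01530), a light-harvesting protein, gave −0.94 ± 0.10 and RCA (AT2G39730), Rubisco activase, −0.57 ± 0.10. That list's median was −0.57 (adjusted p = 0.0016), and the call was lost at adjusted p = 0.081 with an estimated correlation. The same held for heat shock, where 4 of 5 genes rose, 4 also adjusted over the list alone (median 0.73, adjusted p = 0.0083, adjusted p = 0.073 with an estimated correlation). Of the 5, 3 lay below the 40th percentile in both groups. Starch and sucrose metabolism (2 of 3 rose), iron deficiency (1 rose and 2 fell of 4), hypoxia (2 rose and 1 fell of 3), auxin response (1 of 4 fell) and cell cycle (0 of 3 passed) did not pass, with adjusted p between 0.0865 and 0.721. Cell cycle had a median of −0.011 beside a mean of 0.035 and a test upward.

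**Figure D1:**
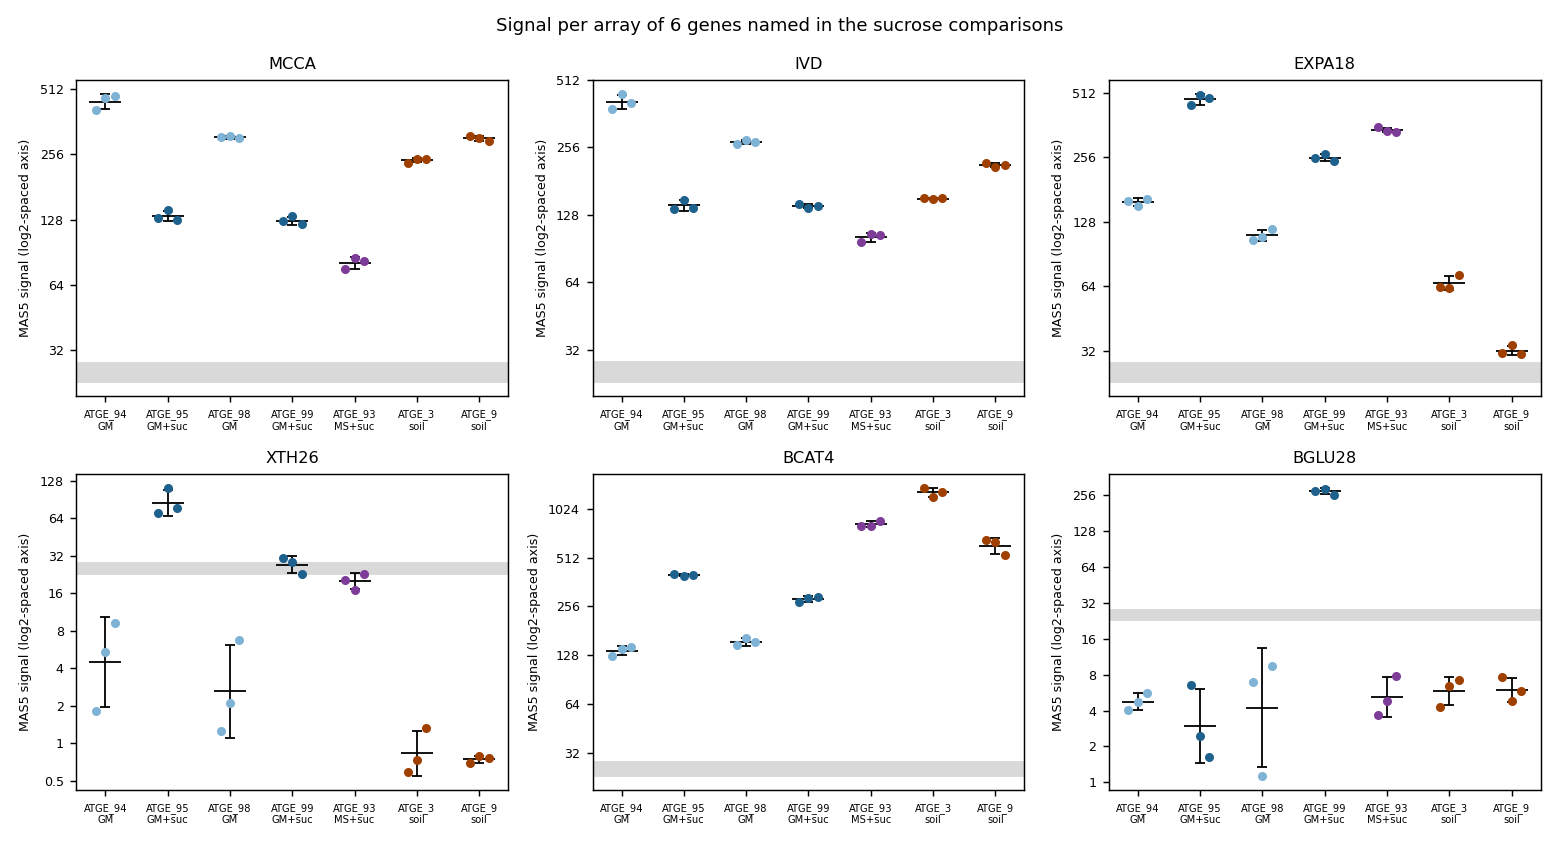
Signal (log axis) of MCCA, IVD, EXPA18, XTH26, BCAT4 and BGLU28 in the 7 groups, where points are arrays, dashes and bars the mean ± SD of log2 signals over 3 arrays, and the grey band the arrays' 40th percentiles (22.9 to 28.0). MCCA and IVD lay lower, and EXPA18 and BCAT4 higher, in ATGE_95 and ATGE_99 than in ATGE_94 and ATGE_98, and BGLU28 lay above the band in ATGE_99 alone.

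In all, 5251 of 15284 probe sets passed, 2321 higher and 2930 lower with sucrose, and 563 of them by at least 2-fold (280 higher, 283 lower). Centring each array on its median turned that balance to 3085 higher and 2160 lower, so the split between directions rests on the scaling. Among plastid-encoded probe sets 14 rose and 12 fell of 66, and mitochondrion-encoded ones rose in 4 and fell in 2 of 16 (adjusted p = 0.431 for each).

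In the later plate sets, ATGE_99 against ATGE_98, the same question gave a rise in BGLU28 (AT2G44460), a beta-glucosidase known from sulfur deficiency. It lay at 276 ± 16.3 with sucrose (SD, n = 3) and below the 40th percentile at 5.88 ± 4.31 without, at least 10.6-fold higher. OCT1 rose 15.3-fold, from 25.5 ± 6.07 to 388 ± 73.4, and AT5G20790 16.1-fold, from 31.8 ± 4.08 to 511 ± 52.9. SWEET14 (AT4G25010), of the SWEET family of sugar transporters, was at least 1.64-fold higher at 42.8 ± 3.36, and AT5G04120 at least 6.59-fold at 172 ± 14.1. MCCA fell 2.42-fold, from 306 ± 4.83 to 126 ± 5.42, and IVD 1.93-fold, from 271 ± 6.12 to 140.2 ± 2.83. Among the other falls, AT1G73120 was at least 2.34-fold lower than its 64.7 ± 1.396, AT5G48430 fell 4.76-fold, and AT3G12900, a gene of coumarin synthesis under iron deficiency, was at least 1.33-fold lower. GH3.3 (AT2G23170), which conjugates auxin to amino acids, was at least 1.198-fold lower than its 33.3 ± 2.95 on GM alone, and the defensin gene PDF1.4 (AT1G19610) at least 1.38-fold lower than its 38.4 ± 3.75.

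By list, sugar starvation fell in 4 of 4, also 4 adjusted over the list alone (median log2 −0.96, camera adjusted p = 4.0e-09, adjusted p = 0.0032 with an estimated correlation). AT3G15450 gave −0.97 ± 0.06 and AKINBETA1 −0.79 ± 0.08. Root hair rose in 5 of 5, again 5 adjusted over the list alone (median 1.14, or 0.80 with dim members at their bound, adjusted p = 8.5e-06, adjusted p = 0.0032 with an estimated correlation). EXPA18 rose 2.30-fold to 254 ± 9.28 and AT1G30870 2.21-fold to 653 ± 66.3. Glucosinolate synthesis rose in 3 of 4, or 4 adjusted over the list alone (median 0.53, adjusted p = 0.0018), and this was lost at adjusted p = 0.069 with an estimated correlation. Its examples were BCAT4 at 0.88 ± 0.08, GSTU20 at 0.76 ± 0.13 and AT2G31790 at 0.31 ± 0.09, the last lost without ATGE_98 replicate 2 (0.26, adjusted p = 0.054). The other 7 lists did not pass, with adjusted p between 0.137 and 0.402. Photosynthesis had 1 rise and 2 falls of 9, heat shock 2 rises of 5, and hypoxia 2 rises and 1 fall of 3. Iron deficiency had 2 falls of 4, auxin response 1 rise and 2 falls of 4, starch and sucrose metabolism 1 rise of 3, and cell cycle 0 of 3, or 2 rises adjusted over the list alone.

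Here 3755 probe sets passed, 1939 higher and 1816 lower with sucrose, 439 by at least 2-fold (290 higher, 149 lower). The balance of all calls was 2004 to 2015 under quantile normalization and 1802 to 1913 under median centring. Among the 66 plastid-encoded probe sets 2 rose and 4 fell (adjusted p = 0.295), and 0 of 16 mitochondrion-encoded ones passed (adjusted p = 0.29). Of the probe sets, 938 were higher with sucrose in both pairs of groups, where independence would give 294. A further 1066 were lower in both, where it would give 348, and 135 went opposite ways. Across the 15284 probe sets, which are not independent replicates, the 2 sucrose effects correlated with Pearson's r = 0.56 and Spearman's rho = 0.45.

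**Figure D2:**
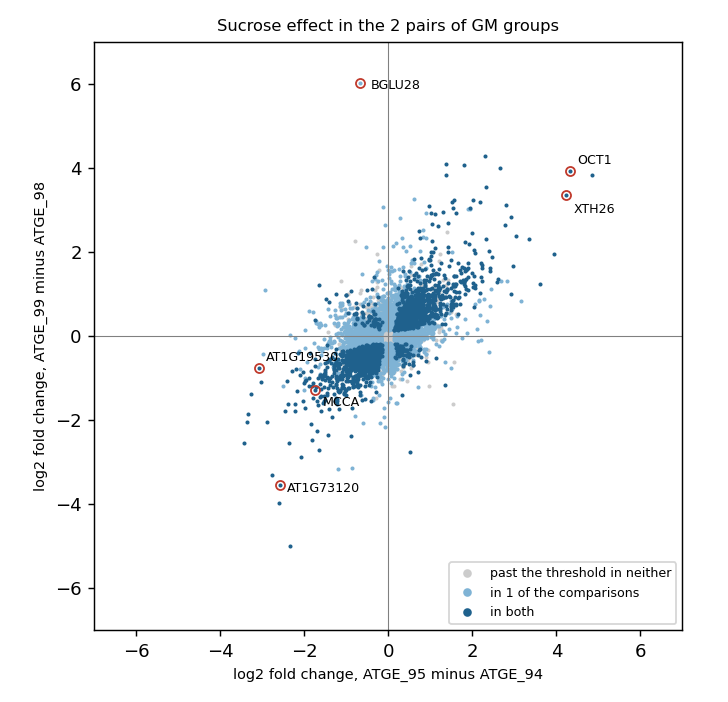
Log2 difference with sucrose in ATGE_99 minus ATGE_98 against that in ATGE_95 minus ATGE_94 for 15284 probe sets, 1 point each, with 6 genes named. OCT1, XTH26 and AT1G73120 lay far from 0 on the same side in both, as fitted values that rest in part on dim groups. XTH26 was dim on GM alone in both pairs. MCCA lay below 0 in both, and BGLU28 was high in the later pair only. The fitted difference between its effects was 6.70 ± 0.84 (log2, SE) and is no bound, since BGLU28 was dim in all these groups but ATGE_99.

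Whether the sucrose effect itself differed between the earlier and the later sets was tested as the difference of the 2 effects, later minus earlier. Genes of glucosinolate synthesis responded less in the later sets: AT2G31790 by 1.05 ± 0.12 (log2, SE, n = 3 per group, adjusted p = 3.4e-06), GSTU20 by 0.84 ± 0.18 (adjusted p = 0.0043) and BCAT4 by 0.67 ± 0.11 (adjusted p = 1.8e-04). AT2G31790 stood at 72.7 ± 3.80 and 187 ± 14.2 without and with sucrose in the earlier sets, and at 58.9 ± 4.16 and 72.8 ± 3.48 in the later. The falls of IVD and MCCA were smaller in the later sets by 0.59 ± 0.09 and 0.47 ± 0.10. AT1G19530 fell 8.47-fold in the earlier sets and from 170.2 ± 9.71 to 101 ± 3.34 in the later, a difference of 2.33 ± 0.21. AT4G21870 was at 45.8 ± 5.32 and 116 ± 9.11 in the earlier sets and at 49.7 ± 4.99 and 22.3 ± 2.70 in the later, a difference of −2.50 ± 0.25. BGLU28 was dim in 3 of the 4 groups, so its fitted difference of 6.70 ± 0.84 is no bound.

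Glucosinolate synthesis passed downward, with 3 of 4 genes past the threshold, also 3 adjusted over the list alone (median −0.76, camera adjusted p = 3.6e-05, adjusted p = 0.037 with an estimated correlation). Photosynthesis passed upward, with 4 of 9, or 6 adjusted over the list alone (median 0.50, adjusted p = 0.0064), but not with an estimated correlation (adjusted p = 0.26). Sugar starvation passed upward with 2 of 4, 2 also adjusted over the list alone (median 0.31, adjusted p = 0.044), and was lost at adjusted p = 0.29 with an estimated correlation and at 0.0947 after median centring. In root hair 1 of 5 passed, EXPA18 at −0.39 ± 0.10, and in heat shock and auxin response 0 did, or 1 fall each adjusted over the list alone. In starch and sucrose metabolism, iron deficiency, cell cycle and hypoxia 0 passed, and the adjusted p of these 7 lists ran from 0.152 to 0.671. Auxin response had a median of 0.083 beside a mean of −0.21 and a test downward. Among mitochondrion-encoded probe sets 1 of 16 fell (median −0.28, adjusted p = 0.036), a list call lost at adjusted p = 0.46 with an estimated correlation and at 0.11 after median centring. Plastid-encoded probe sets rose in 6 and fell in 8 of 66 (adjusted p = 0.0727). The number past the threshold was 1911, 1080 higher and 831 lower, 297 by at least 2-fold. Without ATGE_94 replicate 1 it was 1237 (675 higher), and after median centring the split turned to 721 higher and 1280 lower.

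Harvest stage was compared first on GM alone, ATGE_98 against ATGE_94. In every comparison of stages, stage coincides with the set of plants and with any processing of that set, and cannot be told apart from them. The berberine bridge enzyme-like gene AT5G44400 lay at 140.0 ± 7.06 against a dim 14.1 ± 1.18 (SD, n = 3), at least 5.85-fold higher. AT1G26390 and AT1G26410, of the same family, were at least 1.67-fold and 1.52-fold higher, and the family was not tested. AT4G14060 rose 10.5-fold, from 30.6 ± 4.69 to 318 ± 20.3, AT2G33850 7.30-fold, from 30.2 ± 3.61 to 221 ± 36.2. AT5G53880 was at least 5.15-fold higher at 123 ± 6.94. AT1G73120 fell 4.11-fold, from 269 ± 51.9 to 64.7 ± 1.396, AT3G07720 3.08-fold, from 710.1 ± 48.3 to 231 ± 23.59, AT1G57590 4.04-fold and AT5G35940 3.34-fold. UGT76E2 (AT5G59590), a glycosyltransferase, was at least 1.95-fold lower than its 52.0 ± 13.6.

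Cell cycle genes fell in 3 of 3, also 3 adjusted over the list alone (median log2 −0.56, camera adjusted p = 0.047). AUR1 (AT4G32830), an Aurora kinase, went from 110.0 ± 9.71 to 70.7 ± 2.80, and PRL (AT4G02060), a replication licensing factor, from 87.0 ± 11.2 to 58.8 ± 5.52. AUR2 (AT2G25880) gave −0.41 ± 0.14 and was lost without any of 4 arrays and with only the groups compared in the fit (adjusted p = 0.103). It weakened most without ATGE_94 replicate 1 (−0.27, adjusted p = 0.16), then without ATGE_98 replicate 3 (−0.34, 0.091), ATGE_94 replicate 2 (−0.36, 0.084) and ATGE_98 replicate 2 (−0.40, 0.058). Root hair genes fell in 4 of 5, also 4 adjusted over the list alone (median −0.61, adjusted p = 0.047). EXPA18 gave −0.52 ± 0.07, AT1G30870 −0.61 ± 0.11 and EXPA7 −0.69 ± 0.19. Neither call held with an estimated correlation (adjusted p = 0.12 for each), and both ended at adjusted p between 0.0529 and 0.056 under 4 other settings. Plastid-encoded probe sets rose in 35 and fell in 2 of 66, or 36 and 3 adjusted over the list alone (median 0.51, adjusted p = 1.0e-05, adjusted p = 0.16 with an estimated correlation), and mitochondrion-encoded ones rose in 13 of 16, or 14 adjusted over the list alone (median 1.03, adjusted p = 1.0e-05, adjusted p = 0.063 with an estimated correlation). The 5S ribosomal RNA probe set lay higher as well, at 65.5 ± 5.13 against 16.0 ± 8.34. The other 8 lists did not pass, with adjusted p from 0.172 to 0.917. Sugar starvation had 1 rise and 2 falls of 4, or 3 falls adjusted over the list alone, and hypoxia 2 rises and 1 fall of 3. Photosynthesis had 1 rise and 2 falls of 9, starch and sucrose metabolism 1 rise and 1 fall of 3, and heat shock 1 rise of 5, in a gene dim in both groups. Iron deficiency and glucosinolate synthesis had 1 fall of 4 each, and auxin response 0 of 4. Photosynthesis had a mean of 0.083 beside a median of −0.0032 and a test downward. A total of 6368 probe sets passed, 3253 higher and 3115 lower in ATGE_98, 735 by at least 2-fold (536 higher, 199 lower). The balance of all calls turned to 2920 higher and 3505 lower under quantile normalization and to 2817 and 3557 under median centring.

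With sucrose in the medium, ATGE_99 against ATGE_95, the later set was higher in HIS1-3 (AT2G18050), a linker histone, which rose 9.73-fold, from 86.1 ± 10.4 to 835 ± 32.7 (SD, n = 3). OCT1 rose 9.57-fold, from 40.4 ± 5.97 to 388 ± 73.4. BGLU28 was at least 11.8-fold higher and AT3G05400 at least 10.96-fold higher at 257 ± 11.8. JRG21 (AT3G55970), an oxygenase, was at least 1.26-fold higher at 29.5 ± 1.91, and the berberine bridge enzyme-like gene AT1G26420 at least 1.85-fold at 43.4 ± 4.01. Lower were AT1G62510, 5.77-fold, from 169 ± 9.94 to 30.3 ± 9.27, AT1G19900, 3.75-fold, from 243 ± 5.92 to 64.9 ± 4.48, and AT5G23840, 3.62-fold, from 396 ± 6.82 to 112 ± 26.3. AT4G21870 was at least 4.16-fold lower than its 116 ± 9.11 and the carboxylesterase gene CXE20 (AT5G62180) at least 1.66-fold lower.

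Glucosinolate synthesis fell in 4 of 4, also 4 adjusted over the list alone (median log2 −0.69, camera adjusted p = 0.0037, adjusted p = 0.090 with an estimated correlation), with AT2G31790 at −1.36 ± 0.09, GSTU20 at −0.89 ± 0.13 and BCAT4 at −0.50 ± 0.08. Root hair fell in 4 of 5, also 4 adjusted over the list alone (median −0.90, adjusted p = 0.0058, adjusted p = 0.090 with an estimated correlation), with EXPA7 down 2.17-fold from 331 ± 25.5 to 153 ± 11.1 and EXPA18 1.87-fold. Photosynthesis rose in 6 of 9 genes, LHCB4.1 by 1.103 ± 0.099 among them, while the list missed the threshold (adjusted p = 0.0876). So did cell cycle with 2 of 3 lower, or 3 adjusted over the list alone (0.0876), iron deficiency with 3 of 4 lower (0.0932), and the remaining 5 lists (adjusted p from 0.505 to 0.938). These were starch and sucrose metabolism (1 rose, 2 fell of 3), sugar starvation (1 of 4 rose, 0 adjusted over the list alone), hypoxia (1 rose, or 2 adjusted over the list alone, and 1 fell of 3), heat shock (2 of 5 fell, 1 of them dim in both groups) and auxin response (1 rose, 1 fell of 4, with a median of 0.18, a mean of −0.10 and a test downward). Sugar starvation had a mean of 0.014 beside a median of −0.0099. Plastid-encoded probe sets rose in 28 and fell in 1 of 66, also adjusted over the list alone (median 0.40, adjusted p = 0.0089, adjusted p = 0.36 with an estimated correlation), and mitochondrion-encoded ones rose in 9 of 16, or 10 adjusted over the list alone (median 0.56, adjusted p = 0.016, adjusted p = 0.36 with an estimated correlation), and the 5S ribosomal RNA probe set lay at 61.8 ± 8.72 against 28.1 ± 8.84.

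Of the 7327 probe sets that passed, 4270 were higher and 3057 lower in ATGE_99, 971 by at least 2-fold (719 higher, 252 lower). That excess of higher values turned to 3235 against 3721 under quantile normalization and to 2934 against 4364 under median centring, which moved the median of all probe sets from 0.077 to −0.046. Under median centring 558 were higher and 386 lower by at least 2-fold. With and without sucrose, 2230 probe sets were higher in the later set in both comparisons, against 909 under independence, 1890 were lower in both, against 623, and 152 went opposite ways. Across probe sets the stage differences correlated with r = 0.71 (rho = 0.66). An effect of set or processing shared by both pairs would also give such a correlation, so it does not single out stage.

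On soil, ATGE_9 against ATGE_3 asked about harvest stage, with the limit that the ATGE_3 tissue carried soil. Small heat shock proteins were far higher in ATGE_9. AT1G54050 rose 27.7-fold, from 42.1 ± 6.83 to 1157 ± 23.3 (SD, n = 3). AT1G53540 was at least 9.58-fold higher at 253 ± 33.6, AT5G51440 at least 7.08-fold at 186 ± 8.31, and AT2G29500 at least 11.5-fold at 303 ± 25.4. The DnaJ-type chaperone gene AT2G20560 was at least 16.4-fold higher at 432 ± 17.2, and AT5G48570, an immunophilin gene, rose 10.5-fold, from 43.1 ± 2.17 to 453 ± 7.92. AT1G67865 was at least 22.4-fold and AT1G67860 at least 2.23-fold higher, and AT1G14200 rose 18.3-fold, from 33.2 ± 3.77 to 604 ± 47.5. Falls were smaller. AT1G59740 fell 4.44-fold, from 166 ± 8.32 to 37.5 ± 4.33, AT5G26270 4.05-fold and AT4G01390 3.90-fold. AT1G51830 was at least 2.61-fold lower than its 66.1 ± 10.1, SCPL32 (AT1G61130), a serine carboxypeptidase-like protein, at least 3.39-fold lower, and TPS-CIN (AT3G25830), a cineole synthase, at least 1.59-fold lower than its 40.2 ± 5.18.

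**Figure D3:**
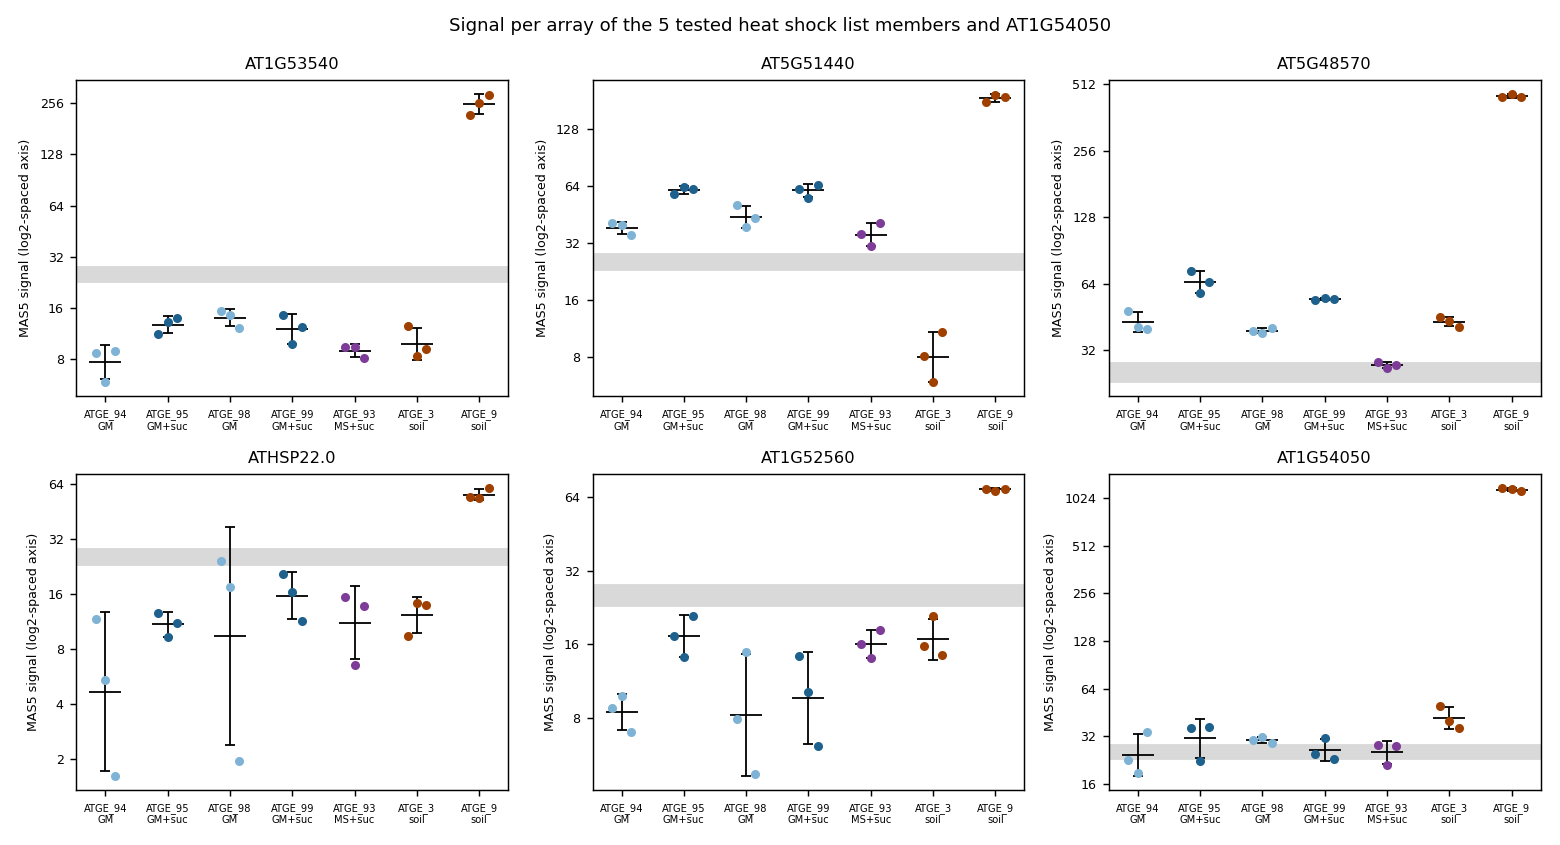
Signal (log axis) of 6 heat shock genes in the 7 groups, where points are arrays, dashes and bars the mean ± SD of log2 signals over 3 arrays, and the grey band the arrays' 40th percentiles (22.9 to 28.0). In AT1G54050 the ATGE_9 arrays averaged 1157, against 42.1 in ATGE_3, and in AT5G48570 453 against 43.1.

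The heat shock list rose in 5 of 5, also 5 adjusted over the list alone (median log2 3.39, or 2.82 with dim members at their bound, camera adjusted p = 9.0e-10, adjusted p = 7.8e-04 with an estimated correlation). Glucosinolate synthesis fell in 4 of 4, also 4 adjusted over the list alone (median −0.74, adjusted p = 1.2e-04, adjusted p = 0.033 with an estimated correlation), and BCAT4 went from 1293 ± 77.5 to 609 ± 67.7. Sugar starvation rose in 3 of 4, also 3 adjusted over the list alone (median 0.42, adjusted p = 0.0020, adjusted p = 0.048 with an estimated correlation), with AKINBETA1 at 0.62 ± 0.08. Hypoxia genes rose in 2 of 3, or 3 adjusted over the list alone (median 0.57, adjusted p = 0.0024, adjusted p = 0.040 with an estimated correlation), with PDC2 (AT5G54960), a pyruvate decarboxylase, at 0.89 ± 0.08 and AT3G03270 at 0.57 ± 0.10. Cell cycle fell in 3 of 3, also 3 adjusted over the list alone (median −0.52, adjusted p = 0.017, adjusted p = 0.047 with an estimated correlation), with PRL at −0.52 ± 0.10. Root hair (2 of 5 fell), photosynthesis (1 rose, or 2 adjusted over the list alone, and 4 fell of 9), iron deficiency (2 of 4 fell), starch and sucrose metabolism (1 rose, 2 fell of 3) and auxin response (1 of 4 fell, with 1 rise besides when adjusted over the list alone) did not pass (adjusted p from 0.105 to 0.655). Starch and sucrose metabolism had a median of −0.18 beside a mean of 0.24 and a test upward. Plastid-encoded probe sets rose in 14 and fell in 5 of 66, or 16 and 5 adjusted over the list alone (median 0.14, adjusted p = 0.034, adjusted p = 0.49 with an estimated correlation) and mitochondrion-encoded ones rose in 4 of 16, or 6 adjusted over the list alone (median 0.39, adjusted p = 0.0022, adjusted p = 0.21 with an estimated correlation). The 5S ribosomal RNA probe set stood at 216 ± 31.8 in ATGE_3 and 174 ± 2.37 in ATGE_9, and that for 25S at 47.8 ± 29.9 and 1019 ± 475. The plastid call also ended at adjusted p = 0.076 under quantile normalization, 0.057 under median centring and 0.059 with a pseudocount.

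In this comparison 4081 probe sets passed, 1742 higher and 2339 lower in ATGE_9, 541 by at least 2-fold (252 higher, 289 lower). The balance of all calls was 1932 to 2229 under quantile normalization and 1950 to 2023 under median centring. The overlap with the plate stage differences was weak. Against the pair on GM alone, 708 probe sets were higher in both (371 under independence), 752 lower in both (477) and 787 opposite, with r = 0.11 across probe sets. Against the pair with sucrose, 880 were higher in both (487), 901 lower in both (468) and 720 opposite, with r = 0.17. Numbers under independence were not computed for the opposite calls, so 787 and 720 by themselves show no excess of them.

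Growth on soil was then set against growth on GM, the mean of ATGE_3 and ATGE_9 against the mean of ATGE_94 and ATGE_98. A PR-1-like gene, AT4G33720, lay at 1507 ± 850.0 on soil against a dim 4.06 ± 3.45 on GM (SD, n = 6), at least 51.8-fold higher, with 732 ± 50.1 in ATGE_3 and 2282 ± 38.7 in ATGE_9. AT5G52050 was at least 4.78-fold higher at 126 ± 45.4 and AT5G52760 at least 3.01-fold at 80.2 ± 31.1. Much lower on soil were the peroxidase gene AT5G64120, 58.1-fold, from 1737 ± 95.6 to 30.1 ± 4.22, and AT3G57020, a strictosidine synthase-like gene, at least 56.8-fold below its 1461 ± 91.3. Among the other large falls were CHIL (AT5G05270), chalcone isomerase-like, at least 18.9-fold below its 488 ± 39.2, and UGT84A1 (AT4G15480), a hydroxycinnamate glucosyltransferase, at least 3.61-fold below its 93.7 ± 14.1. AT5G62210 was at least 9.86-fold and AT2G41380 at least 9.62-fold lower.

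Photosynthesis genes fell in 9 of 9 on soil, also 9 adjusted over the list alone (median log2 −2.15, or −1.79 with the dim groups of 7 members at their bound, camera adjusted p = 6.2e-05), although the call was lost with an estimated correlation (adjusted p = 0.097). RCA went from 240 ± 23.7 to 31.1 ± 10.3, at least 7.53-fold lower since ATGE_9 was dim, LHCB4.1 went from 238 ± 54.5 to 52.9 ± 7.70 (4.44-fold) and ATPC1 (AT4G04640), a chloroplast ATP synthase subunit, from 265 ± 35.0 to 50.5 ± 8.41 (5.26-fold). Cell cycle genes rose in 3 of 3, also 3 adjusted over the list alone (median 1.02, adjusted p = 0.033, adjusted p = 0.10 with an estimated correlation), AUR2 2.97-fold and AUR1 2.02-fold. Root hair genes fell in 4 of 5 and SCN1 rose by 0.13 ± 0.04, the same numbers adjusted over the list alone (median −1.70, adjusted p = 0.034, adjusted p = 0.16 with an estimated correlation), with EXPA18 2.87-fold and AT1G30870 3.68-fold lower. XTH26, counted among the 4, was dim in all 4 groups, so no fall was measured for it. Setting its soil groups at their 40th percentile would enter it as a rise and give a list median of −1.52. Glucosinolate synthesis rose in 3 of 4, or 4 adjusted over the list alone (median 0.95, adjusted p = 0.033, adjusted p = 0.17 with an estimated correlation), with BCAT4 6.10-fold higher at 951 ± 380.0 against 146 ± 12.6. Sugar starvation fell in 4 of 4, also 4 adjusted over the list alone (median −0.49, adjusted p = 0.034, adjusted p = 0.17 with an estimated correlation), with IVD at −0.89 ± 0.05.

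The heat shock list rose in 4 of 5 on soil, also 4 adjusted over the list alone (median 1.99, or 0.44 with the 3 members dim on all GM arrays at their bound, adjusted p = 0.048, adjusted p = 0.17 with an estimated correlation). This rested on ATGE_9, since with ATGE_3 as the soil side AT5G48570 gave 0.07 (adjusted p = 0.45), AT1G53540 was dim in all the groups compared, and the list turned downward (adjusted p = 0.829). Quantile normalization also ended the list call (adjusted p = 0.054). With ATGE_9 as the soil side, sugar starvation (adjusted p = 0.13) and glucosinolate synthesis (adjusted p = 0.093) no longer passed. Hypoxia did not pass (adjusted p = 0.794), with AT4G17260, a lactate dehydrogenase gene, at 0.79 ± 0.06, AT3G03270 at 0.60 ± 0.07 and PDC2 at −2.38 ± 0.05, a median of 0.60 beside a mean of −0.33. Starch and sucrose metabolism (1 rose, 2 fell of 3, 0.494), iron deficiency (1 rose, 2 fell of 4, 0.548) and auxin response (2 rose, 2 fell of 4, 0.697) did not pass either. Plastid-encoded probe sets rose in 14 and fell in 33 of 66 (adjusted p = 0.0519), and mitochondrion-encoded ones rose in 2 and fell in 7 of 16 (adjusted p = 0.118).

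As many as 11394 probe sets passed, 5992 higher and 5402 lower on soil, 2767 by at least 2-fold (1312 higher, 1455 lower). With ATGE_9 alone as the soil side 10270 passed, and with ATGE_3 alone 10894. Substrate went together with temperature (23 against 20 °C) and with a difference in the array controls. The dap control, a bacterial transcript with a poly(A) tail that is added to RNA before labelling, gave 266 ± 71.9 on the 15 plate arrays and 1.70 ± 1.67 on the 6 soil arrays (SD), whereas the cre control, added after labelling, gave 2479 ± 406 and 2358 ± 207. The soil and plate arrays thus differed in the controls their samples carried into labelling, and this comparison cannot tell substrate apart from such a difference in processing.

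**Figure D4:**
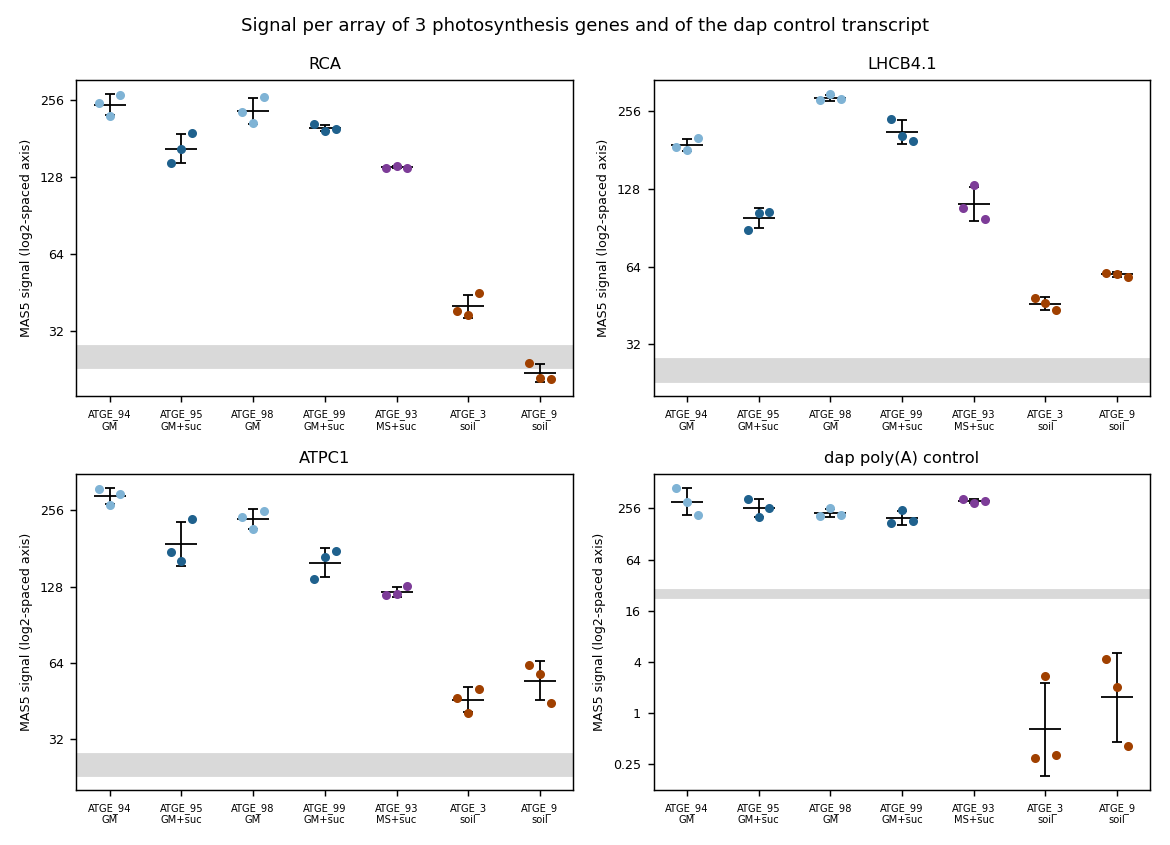
Signal (log axis) of RCA, LHCB4.1, ATPC1 and the dap control in the 7 groups, where points are arrays, dashes and bars the mean ± SD of log2 signals over 3 arrays, and the grey band the arrays' 40th percentiles (22.9 to 28.0). The dap control lay between 175 and 443 on plate arrays and between 0.30 and 4.39 on soil arrays, which also held the lower photosynthesis signals.

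Last, ATGE_93 (long day, 1x MS, 1% sucrose) was set against the mean of ATGE_95 and ATGE_99 (continuous light, 0.5x GM, 5% sucrose), a comparison in which day length, medium, sucrose and temperature all differ. The set of plants differs as well. The labels give no age for ATGE_93, while ATGE_95 and ATGE_99 are an earlier and a later harvest. The PR-1-like gene AT4G33720 was at least 14.9-fold higher at 394 ± 20.8 (SD, n = 3), with 4.28 in ATGE_95, below the 40th percentile, and 29.7 in ATGE_99. The oxygenase gene AT1G52820 was at least 12.1-fold higher at 635 ± 20.9, with a dim 16.4 in ATGE_95 and 118 in ATGE_99. Its relatives AT1G52790 and AT1G80320 were at least 2.34-fold and 2.25-fold higher, and AT5G38910 at least 8.22-fold higher at 245 ± 10.1. SP1L2 (AT1G69230), of the SPIRAL1-like family of microtubule proteins, rose 6.84-fold, from 35.3 ± 15.9 to 221 ± 14.2. HIS1-3 fell 6.37-fold, to 42.2 ± 5.88 from a mean of 460.4 that joined 86.1 in ATGE_95 and 835 in ATGE_99. TPS-CIN fell 4.33-fold, from 442 ± 222 to 91.5 ± 16.5, and PRX52 (AT5G05340), a peroxidase, was at least 1.97-fold lower. Lower as well were the plastid genes rpl14 (4.72-fold) and atpH (4.08-fold) and the mitochondrial gene nad9 (at least 3.09-fold below its 72.7 ± 10.9).

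Plastid-encoded probe sets fell in 52 and rose in 2 of 66, or 53 and 3 adjusted over the list alone (median log2 −0.97, camera adjusted p = 5.6e-13, adjusted p = 0.028 with an estimated correlation), and mitochondrion-encoded ones fell in 15 of 16, also adjusted over the list alone (median −1.59, adjusted p = 5.1e-09, adjusted p = 0.015 with an estimated correlation). The probe set for 5S ribosomal RNA lay at 1.39 ± 0.779 in ATGE_93, 28.1 ± 8.84 in ATGE_95 and 61.8 ± 8.72 in ATGE_99. Glucosinolate synthesis rose in 3 of 4 genes, also 3 adjusted over the list alone (median 1.01, adjusted p = 7.4e-04, adjusted p = 0.10 with an estimated correlation), with BCAT4 2.44-fold higher at 822 ± 34.4 and GSTU20 3.12-fold higher at 399 ± 10.5. Sugar starvation fell in 4 of 4, also 4 adjusted over the list alone (median −0.56, adjusted p = 0.0034, adjusted p = 0.11 with an estimated correlation), with MCCA at −0.68 ± 0.06, AT3G15450 at −0.66 ± 0.05 and IVD at −0.47 ± 0.06. Iron deficiency had 2 rises of 4 (adjusted p = 0.0668) and photosynthesis 5 falls of 9 (0.26). Heat shock had 2 falls of 5, or 3 adjusted over the list alone (0.214), cell cycle 2 rises of 3 (0.214) and hypoxia 2 rises of 3 (0.27). Auxin response had 2 falls of 4 (0.345), starch and sucrose metabolism 1 rise of 3 (0.503, with a median of −0.052, a mean of 0.16 and a test upward) and root hair 0 of 5 (0.731).

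Past the threshold were 7516 probe sets, 3202 higher and 4314 lower in ATGE_93, 557 by at least 2-fold (192 higher, 365 lower). Median centring, which moved the median of all probe sets from −0.054 to 0.050, turned the split of all calls to 4407 higher and 3008 lower. By at least 2-fold, 260 were then higher and 276 lower, and 246 and 287 under quantile normalization.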

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

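The tests of scaling, of a labelling batch, of the later harvest, of warmth or handling, of fewer plastids and of the labelling of RNA without a poly(A) tail were chosen only after their results were seen, and those of shoot tissue, of a single array and of other splits before.

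The sucrose effect differed between the earlier and the later plate sets by a direct test of the difference in 1911 probe sets. Of all 100 pairs of splits of the 12 arrays within each pair of groups, 1 gave as many probe sets, the real one, and the highest other gave 1162. Such splits also break the sucrose effects themselves, so they say nothing on chance for the difference of the effects. The actin 3'/5' ratio was 2.81 ± 0.783 in ATGE_95, 1.85 ± 0.426 in ATGE_94, 2.07 ± 0.185 in ATGE_98 and 1.58 ± 0.106 in ATGE_99 (SD, n = 3). Whether RNA integrity contributed to the difference of the effects was not tested. The lists that differed were glucosinolate synthesis (camera adjusted p = 3.6e-05), photosynthesis (adjusted p = 0.0064) and sugar starvation (adjusted p = 0.0435), and with an estimated correlation only the list of glucosinolate synthesis passed (adjusted p = 0.037, against 0.26 and 0.29). The named genes with a more positive effect in the later sets were BGLU28 (6.70, log2), AT1G60200 (2.87), AT4G14980 (2.53), AT1G19530 (2.33), AT5G62330 (2.25), AT2G27900 (2.24), the isocitrate lyase gene ICL (2.08), AT3G57160 (2.05), LHCB4.3 (1.14), PSAN (0.63), IVD (0.59), LHCB4.1 (0.50) and MCCA (0.47). A more negative effect was found for AT3G63360 (−3.14), AT4G21870 (−2.50), AT1G59850 (−2.36), rpl20 (−1.94), AT2G39980 (−1.90), PDF1.4 (−1.87), AT1G15480 (−1.80), AT1G62320 (−1.78), AT2G31790 (−1.05), GSTU20 (−0.84) and BCAT4 (−0.67). AT4G14980, AT5G62330, AT3G63360 and AT1G15480 lay below the 40th percentile on all arrays of the 4 groups. BGLU28, AT3G57160, PDF1.4 and AT1G62320 did so in 3 groups, AT1G60200, AT2G27900, AT1G59850 and AT2G39980 in a pair of them, and ICL and AT4G21870 in 1. The differences of all these genes are fitted values that rest in part on background, and none is a bound.

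Control probe sets, which no comparison used, carried a signal that followed the substrate. The poly(A) controls averaged 265.5 (dap), 38.9 (lys), 36.9 (phe) and 112 (thr) on the 15 plate arrays, against 1.70, 5.07, 3.14 and 3.34 on the 6 soil arrays. The probe set for 5S ribosomal RNA averaged 195 ± 30.7 on soil arrays and 34.6 ± 26.8 on plate arrays.

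Photosynthesis transcripts lay lower on soil than on GM, with a list median of −2.15 (log2), or −1.79 with dim groups at their bound. The camera call of the list was lost with an estimated correlation (adjusted p = 0.097). The values argue against the scaling as the cause, since the fitted median was still −2.14 under the scaling that brought it closest to 0. Uneven pieces of shoot in the GM samples would make the list mean vary between arrays, and the largest SD over a GM group was 0.089 (log2) beside a difference of −1.98, but an even carry-over would give the same, so shoot tissue stays open. A labelling batch stays open too, since the mean dap signal was 156 times as high on plate as on soil arrays and that split coincides with substrate. The soil arrays were dim in dap (at most 4.39), so the ratio rests on background and is no bound. The labels give substrate and temperature as differences and humidity for soil only, and all of these remain open and untested.

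Heat shock transcripts lay higher in ATGE_9 than in ATGE_3. A single array is excluded as the cause, since the lowest ATGE_9 array exceeded the highest ATGE_3 array by 3.25 (log2) in the list mean, and so is the scaling, with a list median of at least 3.42 under either other scaling. A later harvest in general would raise the list on plates as well, where the medians were 0.19 and −0.08. ATGE_9 exceeded the highest of the other 6 groups by 2.61, which is consistent with warmth or handling around harvest but cannot be told apart from any other feature of that group, since handling and group coincide. The soil that came with ATGE_3, and age on soil, remain open and untested.

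Plastid-encoded and mitochondrion-encoded transcripts lay lower in ATGE_93 than on GM with sucrose. The scaling is excluded as the whole cause, since the list median closest to 0 under another scaling was −0.86 (log2). Fewer plastids cannot be the whole cause of both falls, since the median of probe sets taken as mitochondrion-encoded by their symbols was −1.59. That median was not computed with dim probe sets at their bound. Whether fewer plastids account for the plastid-encoded fall by itself was not tested, and the mitochondrial value cannot decide it. Less labelling of RNA without a poly(A) tail may contribute, with the 5S ribosomal RNA probe set lower by a log2 difference of −5.10. That probe set was dim on all ATGE_93 arrays (0.51 to 1.98), so the difference rests in part on background and is no bound. The 25S probe set differed by 2.06, with arrays of ATGE_93 (182 to 1662) and ATGE_95 (91.3 to 1974) overlapping. Neither value decides the question, so the explanation stays open. Day length, medium, sucrose, temperature and set of plants differ as well and were not separated, and the labels give no age for ATGE_93.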

How the results depend on the processing

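Of the alternatives given here, the tests with either soil group alone were chosen only after the data were seen. Over the settings and left-out arrays run, 128 of 129 recomputed counts past the threshold stayed within 1.5 times of those reported. The exception was the difference of sucrose effects without ATGE_94 replicate 1 (1237), and the cause was not tested. Of the counts with at least a 2-fold change, 121 of 129 stayed within 1.5 times. With a pseudocount, which shrinks folds of dim genes, they moved from 563 to 372 (ATGE_95 against ATGE_94), 735 to 466 (ATGE_98 against ATGE_94), 971 to 645 (ATGE_99 against ATGE_95) and 557 to 343 (long day against GM). The filter at the 60th percentile, which tests fewer genes, gave 177 for 297 (difference of sucrose effects) and 639 for 971, and no filter, which tests more, 1489 for 971 and 916 for 557. The 2-fold counts by direction moved as well, such as the lower ones of ATGE_98 against ATGE_94 (199 to 107 with a pseudocount) and of ATGE_99 against ATGE_95 (252 to 386 under median centring). Leaving out 1 array gave 4073 to 5377 probe sets for ATGE_95 against ATGE_94, 2953 to 3267 for ATGE_99 against ATGE_98, 1237 to 2603 for the difference of sucrose effects, 5352 to 6008 for ATGE_98 against ATGE_94, 6264 to 6807 for ATGE_99 against ATGE_95, 3271 to 3523 for the soil sets, 11077 to 11225 for soil against GM and 6403 to 7561 for long day against GM. With the replicate letter as a block the counts were 5155, 3726, 1864, 6322, 7304, 4052, 11370 and 7471. Residuals of arrays with the same letter had a mean correlation of 0.0045 over 63 pairs, with values from −0.0775 to 0.0710. No strong effect shared by letter was thus seen, which does not tell whether arrays were processed in batches by letter. Of the recomputed list tests, 542 kept direction and side of the threshold, 40 lost the call, 13 gained it and 5 reversed. The 542 include tests that had not passed and stayed so. With an estimated correlation alone, 24 calls were lost, and 72 tests kept their side, passed or not. The calls lost there include every list call of soil against GM. The reversed ones were photosynthesis (adjusted p = 0.963 with a pseudocount) and auxin response (0.721 without a filter) in ATGE_98 against ATGE_94, sugar starvation in ATGE_99 against ATGE_95 (0.716 under quantile normalization), and hypoxia (0.871) and heat shock (0.829) in soil against GM with ATGE_3 alone, and only the heat shock list had been past the threshold. Gained without a filter were sugar starvation in ATGE_98 against ATGE_94 (adjusted p = 0.0453), photosynthesis (0.0337), cell cycle (0.0337) and iron deficiency (0.0373) in ATGE_99 against ATGE_95, root hair in the soil sets (0.0454), plastid-encoded probe sets in soil against GM (0.0117) and iron deficiency in long day against GM (0.0237). A pseudocount gained photosynthesis in ATGE_99 against ATGE_95 (0.0474) and iron deficiency in long day against GM (0.0386). The replicate block gained plastid-encoded probe sets in the difference of sucrose effects (0.0421) and in soil against GM (0.039), and ATGE_3 alone gained plastid-encoded (0.0229) and mitochondrion-encoded ones (0.0337) in soil against GM. For the named genes, 3316 values kept their call, 62 lost it and 1 reversed, AT1G53540 in soil against GM with ATGE_3 alone (−0.079, a fitted difference between groups that were all dim and so no measured reversal). These genes were picked from the same data by size of change or adjusted p, which favours keeping the call. In the difference of sucrose effects, 16 of 24 named genes kept it throughout, against 193 of 207 over all comparisons. The reversals with ATGE_3 alone come from leaving out ATGE_9, and for the others the cause was not tested. Among calls that ended, ICL (adjusted p = 0.0474 for the difference of sucrose effects) reached 0.076 under quantile normalization, 0.056 under median centring and 0.0568 with the replicate block, and LHCB4.1 in that comparison 0.064 and 0.053 under those scalings. Left-out arrays ended further calls in the difference of sucrose effects. ICL was lost without any of 9 of the 12 arrays (adjusted p from 0.0654 without ATGE_98 replicate 2 to 0.136 without ATGE_98 replicate 1) and PDF1.4 also without any of 9 (0.0508 without ATGE_95 replicate 2 to 0.0889 without ATGE_94 replicate 2). AT3G63360 was lost without any of 6 (0.051 without ATGE_99 replicate 3 to 0.0737 without ATGE_95 replicate 1) and AT1G15480 without any of 5 (0.0511 without ATGE_95 replicate 1 to 0.0745 without ATGE_99 replicate 3). AT5G62330 was lost without ATGE_99 replicate 1 (0.0578) or 2 (0.0523), AT3G57160 without ATGE_94 replicate 1 (0.059) or ATGE_98 replicate 2 (0.0539), and LHCB4.1 without ATGE_95 replicate 1 (0.0631) or ATGE_99 replicate 1 (0.0715). A pseudocount ended the calls of AT4G14980 (0.0865), AT5G62330 (0.0783) and AT1G15480 (0.0529), and no filter that of PDF1.4 (0.053). With only the groups compared in the fit, AT5G62330 (0.1003), AT3G63360 (0.0668) and AT1G15480 (0.0603) were lost. AT1G53540, dim in both groups of ATGE_95 against ATGE_94, was lost with only these groups (0.101) and without ATGE_94 replicate 2 (0.1009) or ATGE_95 replicate 3 (0.0568). AT5G04730 in the soil sets was lost without any of 5 arrays (0.0533 without ATGE_3 replicate 1 to 0.0681 without ATGE_9 replicate 1). Signal over background limits the genes below the arrays' 40th percentiles of 22.9 to 28.0, for which a fold is a bound or is not given and any log2 difference is a fitted value.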

Other observations

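The test of 20 symbol families and the choice of the families named here were made only after the data were seen, while the single genes below, except SWEET11, belong to lists fixed earlier with too few members for a test. WRKY53 (AT4G23810), a transcription factor of senescence and defence, was lower with sucrose in the later plate sets, at 30.0 ± 6.81 against 79.2 ± 5.06 (SD, n = 3, log2 −1.42), and higher in ATGE_9 than in ATGE_3, at 152 ± 7.02 against 48.5 ± 3.11 (1.65). UGT78D2 (AT5G17050), a flavonoid glucosyltransferase, lay at 20.3 and 17.7 in ATGE_3 and ATGE_9, below the 40th percentile, and at 375 and 277 in ATGE_94 and ATGE_98. Of the dehydrin genes, LTI30 (AT3G50970) was lower on soil than on GM by a log2 difference of −1.69 and COR47 (AT1G20440) by −0.77. GI (AT1G22770), of the evening clock, was lower in ATGE_93 than on GM with sucrose (−0.74), where day length, medium, sucrose, temperature and set of plants all differ. The labels give no hour of harvest. SWEET11 (AT3G48740), a sugar transporter, rose with sucrose in both pairs of sets (0.61 and 0.83), and its list, starch and sucrose metabolism, did not pass (adjusted p = 0.0865 and 0.342). GSO1 (AT4G20140), a receptor kinase of the Casparian strip, was lower in the later plate sets (−0.54 and −0.59), and so was the peroxidase gene AT5G66390 of the xylem list (−0.62 and −0.69). GRX480 (AT1G28480), a glutaredoxin, was higher in the later plate sets (1.54 and 1.16), and WRKY6 (AT1G62300) was lower on soil than on GM (−1.81). GUT2 (AT1G27440), of xylan synthesis, was lower in ATGE_93 than on GM with sucrose (−0.44), and ARR15 (AT1G74890), a cytokinin response regulator, was at least 1.15-fold higher in ATGE_9 than in a dim ATGE_3.

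Families of genes that share a symbol passed the camera test in 16 cases, none of which held with an estimated correlation, and in each case the direction was kept under quantile normalization and median centring. The UGT glycosyltransferases were lower on soil than on GM in 24 and higher in 2 of 30 genes (median log2 −1.17, adjusted p = 2.0e-06, adjusted p = 0.20 with an estimated correlation). In the same comparison ATG genes were lower in 7 of 8 (adjusted p = 0.21 with an estimated correlation), CYP genes lower in 8 and higher in 3 of 13 (0.21), GSTU glutathione transferases lower in 6 and higher in 2 of 9 (0.27), and XTH genes higher in 6 and lower in 1 of 8 (0.20). XTH genes rose with sucrose in 6 and fell in 1 of 8 in the earlier sets (0.099), fell in 5 of 8 between ATGE_95 and ATGE_99 (0.20) and were higher in 6 of 8 in ATGE_93 than on GM with sucrose (0.12). GSTU genes rose with sucrose in 6 and fell in 1 of 9 in the earlier (0.17) and rose in 5 of 9 in the later sets (0.22), GH genes in 6 of 10 in the earlier (0.095) and BGLU genes in 5, with 1 fall, of 10 in the later sets (0.22). ATG genes were higher in 6 of 8 (0.39) and 7 of 8 (0.36) in the later plate sets, with 1 fall each, TBL genes lower in 7 and higher in 1 of 17 in ATGE_99 against ATGE_95 (0.14), and SCPL genes lower in 10 and higher in 1 of 18 in ATGE_9 against ATGE_3 (0.055).

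For the 3 against 3 comparisons there were 10 splits of the arrays, too few for a share under 0.05. The real split was 1 of 10 with as many probe sets in each, with 5251 against 125 in the highest other split for ATGE_95 against ATGE_94, 3755 against 1 for ATGE_99 against ATGE_98, 6368 against 2 for ATGE_98 against ATGE_94, 7327 against 1 for ATGE_99 against ATGE_95, and 4081 against 5 for ATGE_9 against ATGE_3. For soil against GM 1 of 100 splits, the real one, gave as many (11394 against 6593). For long day against GM 2 of 84 splits gave as many as 7516. The other was the split that set the 3 ATGE_99 arrays against the other 6, with 8572, which reflects the structure of the samples. Nearly all of these splits mix arrays of different groups, and only 3 splits of each comparison keep the groups whole, too few for a share under 0.05. These 3, counted only after the other splits had been seen, gave 11394, 6107 and 4654 probe sets for soil against GM and 7516, 5515 and 8572 for long day against GM.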
